A study of Rattus norvegicus with 8 samples.

How the data were processed

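Total RNA from rat sciatic nerve, spinal cord and primary Schwann cells was measured on 8 one-colour Agilent expression arrays, 1 for each of 8 groups. Per the labels, each nerve and cord sample was a pool of 3 Sprague-Dawley animals. The nerve groups were the proximal and distal segments of the transected left sciatic nerve and the contralateral right nerve as control, all on day 1. The cord groups, at day 5, were labelled dorsal hemisection and C-level control. The cultured Schwann cells were unstimulated, or given the S100A8/A9 protein complex at 5 µg/ml for 1 h or 24 h. The only unstimulated culture was that of 24 h, so it stood against both times. The cord labels speak of an injection and the protocol of an injury, and the label of the contralateral nerve mentions a PBS injection site; what was injected is not given in the sources used here.

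The deposited files are of 2 kinds. The scanner files hold spot intensity on a linear scale, made by Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 10.5 of Agilent Feature Extraction. The processed signal among them was background-subtracted by the scanner software, per the file headers, and other columns hold flags and the median signals of the spot and of its local background. All 8 arrays lay on 1 slide and in 1 scan, so no slide or scan batch separates the groups. The value table holds the authors' deposited log2 values for 24938 rows, of which 24894 are probes and 44 are controls. Its columns all have the median 8.03 and equal quartiles, so the table was normalized between all 8 arrays in a manner like quantile normalization, which no label or header records. Regression of a column on the log2 processed signal of the scan that it ranks with gave slopes from 0.92 to 1.11, so the scale is log2 and the direction is that of signal. The offset of its scale and the rule that selected its probes stay unknown: every probe in it was well above background on at least 1 array, and so were 15.4% of the 5473 probes that it leaves out.

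The sources pair samples with arrays in conflicting ways. Each value table column is headed by its sample. Each scanner file is recorded under a sample too. Over 24894 probes, every column ranked almost exactly as 1 scan did (Spearman rho across probes at least 0.99998, next best scan at most 0.993), and for 7 of the 8 samples that scan was recorded under another sample, with a rho of 0.802 to 0.900 to the scan recorded under the sample itself. Only the distal nerve had the same scan in both. The design fixed before the data were examined took the processed signal of the scans as recorded, scaled to the 75th percentile of each array. The value table stood there only as an alternative. That fixed analysis was run in full first. Its tissue markers went against the labels: the neuron list had its highest medians on the arrays recorded as Schwann cells at 24 h and as contralateral nerve. A second full analysis took each scan under the sample whose column it matches, and the last took the value table by its own column headings. The last gives the values reported here. This departs from the fixed design, and it was chosen after the counts, leading genes and list results of all 3 analyses had been seen, with the tissue markers as part of the reason. The marker rule (highest 2 arrays in the neuron list for cord, lowest 3 in the macrophage list for Schwann cells) was also written after the markers had been seen. At the level of tissues the markers tell against the record: as recorded, the neuronal Snap25 stood at -8.71 and -8.73 on the 2 cord arrays and at 3.92 on that of Schwann cells at 24 h, and the globin gene Hbb-b1 at -3.94 and -3.86 on the cord arrays and at 7.75 there (log2 over the 75th percentile; both picked after their values were seen). They do not test labels within 1 tissue, which the sources used here do not settle. Sample names below are those of the column headings, and the results of the fixed design, many of them in the opposite direction, stand with the alternatives.

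Background flags and replicate-spot errors came from the scan that ranks as each column does, not from the scan recorded under the sample. Probes carry no gene name in the files. Their accessions were matched, without versions, to a RefSeq gene table of assembly GRCr8, while the headers name build rn4, so only names were taken and no coordinates are given. Of 30367 probes 18006 matched, with 15159 symbols; of those with deposited values 15213 matched, with 12765 symbols, and 9681 did not. Gene symbols are those of this table and not of the array files. The 2394 symbols outside the value table were not analysed here, except in an alternative with all probes. A gene was represented by its probe with the highest mean over the 8 arrays, and the background flags are those of this probe; 2240 genes had several probes.

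Each comparison took the log2 ratio of 2 columns for genes well above background on at least 1 of the pair (at least a 0.5 share of the unflagged spots of the probe). A side not well above background was set to the higher of its own value and the lowest value well above background on that array, and the ratio is then a bound, written as at least. With 1 array per group there are no replicates, no p-value is possible, and genes were counted at 2-fold, a log2 ratio of 1. The technical error is the pooled SD between spots of a probe at its signal, divided by the root of the number of spots, over both arrays; it leaves out labelling, hybridisation and animals. It covers 15840 probes with 2 spots and 1390 with 10, and was also used for the 13137 with 1. Spot SDs ran from 0.051 log2 for bright probes to 0.953 for dim ones. The number of arrays limits the precision. The counts that this error alone would give in unchanged arrays were simulated 100 times, with the limits for dim genes added after first counts had been seen. In the comparisons, a bound that pointed against the bright side was given no direction. The simulations of unchanged arrays, also those for overlaps, did not apply this rule, so the simulated counts can be too high. For Schwann cells at 24 h they exceed the genes found, so they do not say how many of the genes counted lie within error.

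Before the data were examined, 35 gene lists were fixed, with 792 entries, of which 678 were among the value table genes. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on the mean of both arrays in 20 bins, as a description of these arrays; lists at percentile 97.5 or above, or 2.5 or below, are called apart, and lists with fewer than 5 measured genes have values only. All lists were computed in all 7 comparisons, and 113 of 226 results with a percentile were apart. Lists drawn gene by gene at random would give 11.3. The fixed lists overlap, their genes can move together and comparisons share arrays, so 11.3 is no chance expectation for them. Which lists are described for a comparison, and which count as its main results, was chosen after all of them had been seen. Named genes were, per comparison, the 10 largest and 10 smallest log2 ratios among genes with a symbol other than LOC or RGD names, well above background on both arrays, at least 2-fold apart and with probes of the same sign; up to 4 members of each list reported, by size; and always S100a8, S100a9, Ager and Tlr4. Some genes that this rule takes are not reported here, their places were not refilled, and they still count in totals, lists and overlaps. Overlaps were counted beside the product of both counts over the genes measured in both.

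The steps were tested on simulated data with spot error alone. The changed genes were drawn from those well above background on both arrays, so recovery of dim genes was not tested. These tests also left out the rule that a bound against the bright side has no direction. The shares of unchanged genes found can therefore be too high. In the distal nerve comparison, over 12131 genes, 98.5% of genes changed 3-fold and 1.49% of those changed 1.5-fold were found at least 2-fold apart with the right sign, as were 2.12% of unchanged genes in either direction. For the Schwann cells at 1 h, over 10968 genes, the shares were 95.5%, 7.46% and 2.22%. In those tests 4.5% and 7.5% of random lists were called apart.

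Alternatives fixed beforehand were quantile normalization within a tissue (here applied to values already normalized), median centring, both arrays well above background, no filter and no floor, the mean of the probes of a gene, thresholds of 1.5-fold and 3-fold, and 10 bins. The normexp correction (offset 50) and the outlier spots were fixed beforehand for the scans as recorded, and were run on the scans matched to the columns, as were the 75th percentile scaling and all probes; these and the scans as recorded are alternatives added after seeing the data. As the files hold no mean signal, normexp used the median signal. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.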

Results

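Gene expression was compared in 3 sciatic nerve samples of day 1 after transection, in 2 spinal cord samples of day 5, and in 3 cultures of primary Schwann cells, the glia that ensheath peripheral axons. S100A8 and S100A9 are calcium-binding proteins abundant in neutrophils, and their complex was given to the cultures. Samples are named by the headings of the authors' value table. The scanner files are recorded under other samples for 7 of the 8, and the analysis fixed in advance used that record. It gave opposite directions for many genes, named below for each comparison, and the headings were preferred only after both results had been seen. By rank, each of its pairs compared other columns than those its name gives. Tissue markers went with the label in 8 of 8 samples by the headings and in 1 of 8 as recorded, but do not test labels within 1 tissue. Each direction below therefore rests on those headings being right. Between 66.7% and 77.6% of 30367 probes were well above background on an array, least in the Schwann cells at 1 h and most in the proximal nerve. Arrays of 1 tissue ranked probes more alike (rho across probes 0.951 to 0.993) than arrays of different tissues (0.797 to 0.903). Every group had 1 array, so no difference below has a replicate check, and errors after ± are technical.

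The first comparison asked how the nerve beyond the cut differed from the contralateral nerve. In the distal nerve the lists of leukocyte markers, inflammatory signals and cell cycle genes had higher medians, and those of myelin, fibroblast and cholesterol synthesis genes lower ones. S100a8 (NM_053822) had the largest log2 ratio, 7.33 ± 0.26, and its partner S100a9 (NM_053587) stood at 6.19 ± 0.15. Also among the leading genes were Ptx3, a secreted pattern recognition molecule (5.90 ± 0.15), the immune receptors Clec4a2 (5.91 ± 0.37) and Lilrb4 (5.37 ± 0.15), the interleukin 33 receptor Il1rl1 (5.25 ± 0.26), the hexokinase Hk3 (5.17 ± 0.56), the neuropeptide Ucn2 (5.26 ± 0.15), the linker histone H1f1 (5.27 ± 0.68) and cyclin Ccna2 (5.26 ± 0.26). The lowest ratios were those of Mrgprg (-4.47), Stk32b (-4.44), the olfactory receptor Or5o1 (-4.26), Lrrn1 (-4.22), Cyp26b1, which degrades retinoic acid (-4.02 ± 0.04), Aox4 (-3.94), Cytl1 (-3.94), Fam178b (-3.88), Best1 (-3.73) and Akr1c19 (-3.66). Of 12131 genes measured, 1629 were at least 2-fold higher and 1735 at least 2-fold lower in the distal nerve, where the spot error alone gave 107.4 and 132.4; 306 and 150 of them were bounds. Among 441 such genes with several measured probes, the probes of 35 disagreed in sign. Normexp on the matched scans gave 1002 higher and 1125 lower. With the scans as recorded, 22 of 103 named genes at least 2-fold apart had the opposite sign, and the adipocyte list stood at 3.05.

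Leukocyte lists were higher in the distal nerve. Neutrophil markers had a median log2 ratio of 3.08 (percentile 100), with 12 of 18 genes at least 2-fold higher and 1 lower; Clec4d was at least 5.53. Of 19 monocyte and macrophage markers 15 were higher (median 1.92, percentile 100), among them the scavenger receptors Msr1 (3.78) and Cd163 (2.77) and the Fc receptors Fcgr2b (2.83) and Fcgr1a (2.54). T and NK cell markers (median 1.66) had 16 of 18 higher, including Cd8a (4.79 ± 0.56) and Cd2 (3.08 ± 0.57), with bounds of at least 3.38 for Klrb1b and 2.95 for Cd27. B cell markers (median 2.21) had 5 of 6 higher, with Blnk at 2.77, Fcrla at 2.21, Cd22 at 2.21 and Cd79b at least 2.27. Mast cell markers were not apart (median -0.13, percentile 35.3): Tpsb2 was at -0.99, Ms4a2 at -0.69, Cma1 at -0.21 and Mcpt1 at -0.14.

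Several lists of signalling genes had higher medians too, with fewer than all of their genes at least 2-fold higher. Chemokines, which attract leukocytes, had 14 of 30 higher and 1 lower (median 0.91, percentile 100), with Ccl20 at least 5.75, Ccl2 at 4.16 ± 0.03, Cxcl2 at 4.07 and Cxcl1 at 3.83. Cytokines had 8 of 22 higher and 3 lower (median 0.63, percentile 99.7): Il6 was at least 5.45, and the interleukin 1 antagonist Il1rn, Il10 and Il1b were at 4.51, 3.59 and 3.21. In the list of the TLR, RAGE and NF-kB pathway 14 of 30 were higher (median 0.80, percentile 100), with Tlr6 at 2.97, Tlr2 at 2.93, Tlr7 at 2.40 and Cd14 at 2.31. Of the receptors named for S100A8/A9, Tlr4 was at 1.35 ± 0.10 and Ager, which encodes RAGE, at -0.39 ± 0.17. Interferon response genes had 6 of 29 higher (median 0.59, percentile 99.9), with Oasl at least 3.09, Ifi47 at 1.81, Ifit3 at 1.73 and Psmb8 at 1.55. Matrix metalloproteinases and inhibitors were not apart (median 0.31, percentile 93.7) although 12 of 29 were higher: Mmp9 was at least 3.33, Mmp7 at least 3.32 and Mmp12 at least 3.30. With both arrays well above background the median of this list was -0.59 (percentile 0.36), and with all probes of the matched scans it was 0.38 (98.3). Complement had a low median of -0.60 (percentile 0.41), with 1 of 19 genes 2-fold lower and 4 higher: its leukocyte receptors C3ar1 (3.43), Itgb2 (2.87) and C5ar1 (2.34), and Cfi (1.18). MHC class II presentation was not apart (median 0.31, percentile 90.8, but 0.41 and 98.1 with normexp), with Ciita at 1.41, RT1-DMa at 1.21, RT1-DMb at 1.08 and RT1-Ba at least 0.81.

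Cell cycle genes had the highest list median, 3.29 (percentile 100), and 31 of 33 were higher, including the ribonucleotide reductase subunit Rrm2 (4.84 ± 0.09), the kinase Ttk (4.86 ± 0.79) and the replication licensing factor Cdc6 (at least 4.80). Myelin genes had 18 of 23 lower and no gene higher (median -1.84, percentile 0): Fa2h was at -2.79, Ugt8 at -2.44, Mal at -2.42 and Pllp at -2.26. Cholesterol synthesis had 12 of 25 lower (median -0.96, percentile 0), with Hmgcs1 at -2.36, Tm7sf2 at -1.84, Sc5d at -1.65 and Nsdhl at -1.55. Fibroblast and collagen genes had 11 of 17 lower (median -1.13, percentile 0.01), led by Col14a1 (-2.12), Pi16 (-1.87), Mfap5 (-1.74) and Col1a1 (-1.71). Adipocyte markers had 4 of 14 lower (median -0.86, percentile 0.07), with Pck1 at -3.62, Fasn at -1.98, Scd at -1.71 and Cidea at -1.22. Skeletal muscle markers, of a tissue beside the nerve, had 8 of 16 higher and 3 lower (median 0.97, percentile 99.98): Myl11 was at 2.78, Myh4 at 2.54 and Tnnc2 at 2.40, while Myh7 was at -3.01. Repair Schwann cell genes went both ways and were not apart (median 0.09, percentile 67.6), with Gdnf, a neurotrophic factor, at least 3.89, Igfbp2 at 2.70 and Cdh2 at -2.83.

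Among the other lists, stress genes had a higher median (0.59, percentile 99.9), with 4 of 25 at least 2-fold higher and 9 not above 0; the 4 were heme oxygenase Hmox1 at 4.13 ± 0.03, the metallothioneins Mt2A and Mt1 at 3.27 and 1.44, and Srxn1 at 1.51. With normexp on the matched scans the median of the stress list was 0.24 (percentile 85.6). Hypoxia and glycolysis genes (median 0.22, percentile 91.5), immediate early genes (-0.14, 20.9), the S100 family (-0.33, 9.60), erythroid genes (0.25, 76.5) and ribosomal proteins (0.15, 91.8) were not apart. The hypoxia and glycolysis list was apart in 4 of the alternatives, at 0.37 (98.2) with the mean of probes and at 0.48 (98.6 to 98.7) with the matched scans at the 75th percentile, with outlier spots kept or with all probes. Within them Slc16a3 was at 3.92, Hk2 at 2.12, Aldoc at -2.80, Ndrg1 at -2.07, Fosl1 at least 6.47, Nr4a3 at 1.89, Arc at -2.93, S100a3 at -2.80 and S100b, a Schwann cell marker, at -2.0; Egr4 was at most -2.22. Erythroid values were Alas2 0.66, Ahsp 0.49, Slc4a1 0.45 and Hbb -0.12, whose probes disagreed. Ribosomal values were Rps2 0.88, Rpl15 -0.53, Rpl18 0.51 and Rpl14 0.51. Endothelial and pericyte markers had a median of -0.44 (percentile 2.55), just short of being apart and apart in 4 of the alternatives (2.29 to 2.48), with Cspg4 at -1.84, Cldn5 at -1.64, Myh11 at -1.60 and Eng at 1.29.

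The proximal nerve was set against the same contralateral array. It too had higher medians of the neutrophil, chemokine and cell cycle lists and a lower one of myelin genes. In addition, the median of skeletal muscle genes was very high. S100a8 again had the largest ratio (7.89 ± 0.26), and S100a9 was at 6.50 ± 0.15. Also among the highest were Cxcl2 (6.31 ± 0.15), the lectin-like receptor Olr1 (6.18 ± 0.68) and Ptx3 (6.11 ± 0.15), and the muscle genes Myh4 (6.77 ± 0.56), Myl1 (6.47 ± 0.56), Myl11 (6.36 ± 0.09), Myh8 (5.90 ± 0.09) and Ampd1 (5.69 ± 0.26). The lowest ratios were those of the ribonucleases Rnase1 (-4.96) and Rnase1l2 (-4.67), which are close paralogs, and of Mrgprg (-4.32), Pck1 (-4.22), Lrrn1 (-4.17), Rnf148 (-3.88), Tex13c (-3.87), Fam178b (-3.65), Cytl1 (-3.51) and Pdilt (-3.48). With normexp on the matched scans Rnf148 was at 0.13. Of 12242 genes measured, 1362 were at least 2-fold higher and 1450 lower, against 117.7 and 151.4 from spot error alone. Normexp moved the median of all genes by 0.37, with 1895 higher and 525 lower. With the scans as recorded 3649 were lower, and 51 of 78 named genes had the opposite sign, S100a8 at -8.03 and Cxcl2 at -2.70 among them.

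In the proximal nerve 13 of 18 neutrophil markers were higher and none lower (median 3.11, percentile 100), with Clec4d at least 5.62 and Il1r2 at 4.86. Monocyte and macrophage markers had 12 of 19 higher (median 1.20, percentile 100), with Msr1 at 3.33, Fcgr2b at 2.33, Fcgr1a at 2.25 and Itgam at 2.12. T and NK cell markers (median 1.30, percentile 100) had 12 of 18 higher and 1 lower and included Cd2 at 3.65 and Cd8a at 3.62, with Klrb1b at least 2.94 and Cd3e at least 2.21. Among B cell markers (5 of 6 higher, median 1.22, percentile 99.6) Blnk was at 2.27 and Fcrla at 1.25, with Cd79b at least 1.53. Mast cell markers had a lower median (-0.75, percentile 1.31; 2 of 8 at least 2-fold lower), and microglia markers a higher one (0.52, 99.8; 6 of 19 higher and 1 lower), which was 0.29 (97.0) without a filter or floor and 0.51 (97.4) with normexp. Chemokines had 13 of 30 higher and 1 lower (median 0.64, percentile 100): Ccl20 was at least 6.74, Cxcl1 at 5.00 ± 0.07 and Ccl2 at 4.45 ± 0.03. Cytokines had 10 of 21 higher and 3 lower (median 0.74, percentile 99.97), with Il6 at least 7.36, Il1rn at 5.18, Inhba at 3.82 and Il1b at 3.76. The TLR, RAGE and NF-kB list (13 of 30 higher, median 0.72, percentile 100) held Tlr2 at 2.94, Tlr6 at 2.53, Cd14 at 2.01 and Bcl3 at 1.96, and Tlr4 was at 0.56 ± 0.10 and Ager at -0.13 ± 0.19 (0.39 with normexp). Interferon response genes had 6 of 29 higher and 2 lower (median 0.41, percentile 99.8), with Oasl at least 3.15, Ifit3 at 2.38, Ifi47 at 1.15 and Psmb8 at 1.10. Metalloproteinases and inhibitors were apart here (median 0.49, percentile 99.9; 14 of 30 higher and 4 lower), with Mmp9 at least 4.53, Mmp3 at least 3.70 and Mmp12 at least 3.65, but with both arrays well above background their median was -0.15.

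Cell cycle genes had 29 of 33 higher in the proximal nerve (median 2.44, percentile 100), with Cdc6 at least 4.73, Ccna2 at 4.62, Rrm2 at 4.54 and thymidine kinase Tk1 at 4.26. Myelin genes had 13 of 24 lower (median -1.34, percentile 0), among them Fa2h (-2.24), Ugt8 (-2.02), Nfasc (-1.97) and Mal (-1.90). Cholesterol synthesis (7 of 25 lower and 1 higher, median -0.82, percentile 0) had Hmgcs1 at -1.85 and Idi1 at -1.35. Fibroblast and collagen genes (9 of 17 lower, median -1.07, percentile 0.01) had Pi16 at -1.97, Col14a1 at -1.76, Mfap5 at -1.68 and Postn at -1.55. Skeletal muscle markers had 15 of 17 higher and 1 lower (median 3.32, percentile 100), with Tnnc2 at 5.62 and Atp2a1 at 5.31, and adipocyte markers had 11 of 14 lower (median -1.35, percentile 0), with Scd at -2.57, Fasn at -1.71 and Pparg at -1.56. Complement was low (median -0.55, percentile 0.40; 3 of 19 lower and 5 higher), with C6 at -1.49, but C3ar1 was at 2.45, Itgb2 at 2.28 and C5ar1 at 1.84. Stress genes (0.52, 99.9; 4 of 25 higher) and hypoxia and glycolysis genes (0.48, 99.98; 7 of 25 higher and 2 lower) had higher medians, and oligodendrocyte markers (-1.48, 0; 11 of 16 lower) and nerve injury genes of neurons (-0.46, 1.68; 5 of 16 lower and 3 higher) lower ones; the last list was no longer apart with the mean of probes (-0.27, 6.49) or without a filter or floor (-0.27, 8.36). The S100 family (median -0.14, percentile 25.8, and 0.28 with normexp; S100a3 -1.71, S100b -1.64), immediate early genes (-0.28, 4.62), MHC class II presentation (0.07, 68.4) and repair Schwann cell genes (0.08, 70.3) were not apart. Their named members were Fosl1 at least 6.02, Junb 1.68, Arc -2.90, Egr4 at most -2.52, Ciita 1.32, RT1-DMb 1.09, RT1-DMa 1.08, RT1-Ba at least 1.05, Ucn2 4.20, Cdh2 -2.25, Shh 1.72 and Gdnf at least 1.82.

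Both injured segments shared most of their genes. Of 12069 genes measured in both comparisons 1158 were at least 2-fold higher in both and 1263 lower in both. Independent lists would give 179.2 and 208.4, and unchanged arrays sharing the contralateral array gave 68.4 and 83.3 with spot error alone. Any other feature of the contralateral array enters both ratios alike. It would raise shared and lower opposite moves, so neither count separates a shared injury response from it. Normexp left 763 higher and 477 lower in both, beside 1002 and 1125 in the distal and 1895 and 525 in the proximal comparison. With it, most of the higher distal and of the lower proximal genes were shared, and most of the higher proximal and of the lower distal genes were not. Normexp moved the median of all genes by 0.37 in the proximal comparison, and sets of such unlike size cannot overlap in full. The scans as recorded, which pair other arrays, gave 556 higher and 1804 lower in both. Only 5 genes moved at least 2-fold in opposite directions: Alox12e was higher distally and lower proximally, and Abra, Casq1, Spag11a and Tnmd the reverse, as named after their values were seen.

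Set directly against each other, the segments had 24 of 34 lists apart, and the largest list median was that of skeletal muscle genes, which were lower in the distal nerve. Of 17 muscle markers 15 were at least 2-fold lower distally (median -2.96, percentile 0), and the lowest ratios were those of Ampd1 (-4.50 ± 0.08), Trim54 (-4.42), Myl1 (-4.28), Myh4 (-4.23), Hhatl (-4.22), Myh1 (-4.18), Myf6 (-3.92), Ckm (-3.69), Atp2a1 (-3.66) and Myh8 (-3.59), with Myh2 at most -3.73. The highest were Vom1r15 (5.13 ± 0.40), Dbh, of noradrenaline synthesis (3.15 ± 0.31), Alox12e (2.96), Igfbp2 (2.87), Retnlg (2.60), the eosinophil-type ribonucleases Rnase3 (2.53) and Rnase2 (2.11), Akr1c3 (2.43), the eosinophil chemokine receptor Ccr3 (2.43) and Vip (2.25), which normexp placed at -0.32. Inflammatory lists split, with most of their genes within 2-fold. Medians were higher distally for T and NK cell (0.57, percentile 100), B cell (0.62, 99.97) and mast cell markers (0.49, 99.99). They were slightly higher for the TLR, RAGE and NF-kB list (0.18, 99.9) and complement (0.15, 99.3). Outside these lists, adipocyte markers had a higher median distally (0.55, 100). Neutrophil markers had a lower median distally (-0.22, percentile 0.21; 3 of 18 at least 2-fold lower), with Il1r2 at -1.74, Mmp9 at -1.19, Elane at most -1.25 and Padi4 at 0.84, and so had cytokines (-0.25, 0.02; 2 of 22), with Il6 at -1.90, Inhba at -1.77, Il24 at most -0.93 and Il10 at 0.97. Macrophage markers had a higher median distally (0.50, 100; 1 of 19 at least 2-fold higher), with Cd163 at 1.07, Mrc1 at 1.00, Adgre1 at 0.82 and Fcer1g at 0.73, as had cell cycle genes (0.52, 100; 2 of 33), with Cenpf at 1.09, Nusap1 at 1.00, Ube2c at 0.91 and Ccnb2 at 0.89; normexp placed Cenpf at -0.40. Chemokines were not apart (-0.04, 11.9, but -0.26 and 1.56 with normexp), although Cxcl2 was at -2.23, Cxcl6 at -1.63, Cxcl1 at -1.17 and Ccl12 at 0.99. Metalloproteinases (-0.31, 0; 5 of 30 at least 2-fold lower; Mmp10 at most -1.30, Mmp13 -1.21, Plau -1.04), glycolysis and hypoxia genes (-0.30, 0; 2 of 25; Egln3 -1.33, Slc16a3 -1.05, Vegfa -0.87, Bnip3 -0.76) and myelin genes (-0.45, 0; 0 of 24; Pmp2 -0.88, Cnp -0.84, Mag -0.71) had lower medians distally. S100a8 was at -0.56, S100a9 at -0.31, Tlr4 at 0.79 and Ager at -0.26. Of 12222 genes 151 were at least 2-fold higher and 237 lower distally, against 16.4 and 14.6 from spot error; normexp gave 15 and 2223, and the 75th percentile scaling 88 and 313. Normexp moved the median of all genes by -0.27, and with it the neutrophil, cytokine and metalloproteinase lists were no longer apart, at -0.43 (percentile 4.53), -0.41 (5.48) and -0.43 (17.1). With the scans as recorded 2682 were higher and 1868 lower, 18 of 35 named genes had the opposite sign, and the muscle list stood at 3.20.

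**Figure D1:**
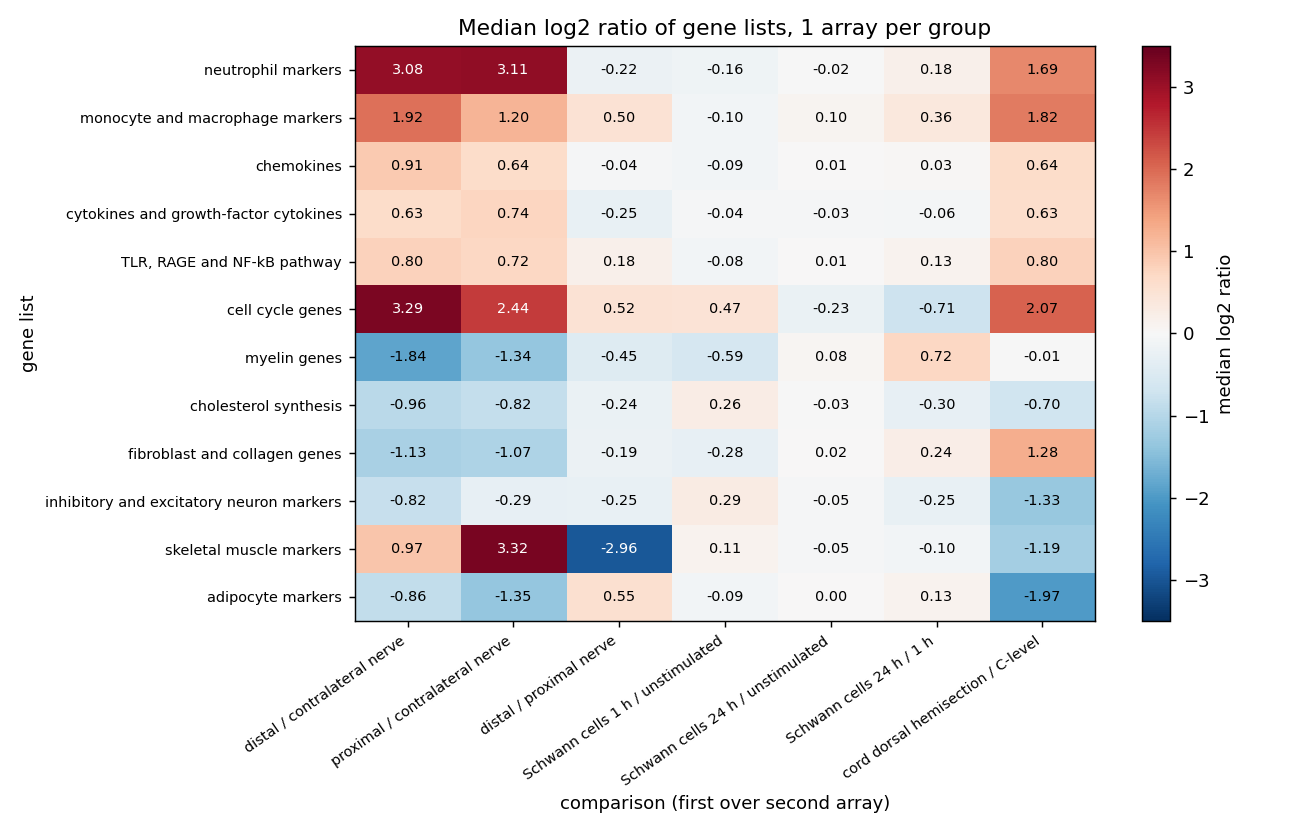
Median log2 ratio of 12 gene lists (rows) in the 7 comparisons (columns), first array over second, with 1 array per group; red is higher and blue lower. Neutrophil markers and cell cycle genes stand at 3.08 and 3.29 in the distal nerve, and all lists lie near 0 for Schwann cells at 24 h.

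The next comparison asked what S100A8/A9 does to cultured Schwann cells within 1 h. A few chemokine genes were far higher after 1 h, without a shift of the chemokine or cytokine lists as wholes. Ccl7 (NM_001007612) was at 4.22 ± 0.57, Ccl2 (NM_031530), which attracts monocytes, at 3.89 ± 0.03, and Cxcl1, which attracts neutrophils, at 2.62 ± 0.16. Next came the chromatin protein Hmga2 (2.62 ± 0.58), Calca, the gene of CGRP (2.60 ± 0.06), the myelin lipid carrier Pmp2 (2.27 ± 0.06), the protease Adamts1 (2.23 ± 0.03), Fam43a (2.21) and Clec2d2l1 (2.0). The lowest ratios were those of the ectonucleotidase Entpd2 (-3.22 ± 0.08), Mfap5 (-2.85 ± 0.08), the noncoding RNA H19 (-2.27), Unc5cl (-2.21), Cxcl14 (-2.10 ± 0.05), Insyn2a (-2.06), the artemin receptor Gfra3 (-2.05 ± 0.05), Alpl (-2.03), Pllp (-2.0) and Tktl1 (-1.89). Of 10968 genes measured 185 were at least 2-fold higher and 147 lower. Simulated spot error alone gave 121.9 and 111.5, which can be too high, as the simulation let bounds point against the bright side. Of the genes found, 59 and 40 were bounds. The 75th percentile scaling gave 182 higher and 227 lower, and normexp 48 and 87. With the scans as recorded 1363 were higher and 1473 lower, and 20 of 29 named genes had the opposite sign, with Ccl2 at -4.70, Ccl7 at -3.90 and Cxcl1 at -4.94. By rank those scans are the contralateral and proximal nerve columns.

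By list, chemokines had 3 of 15 measured genes higher and 1 lower (median -0.09, percentile 18.2). Cytokines (-0.04, 39.6) had 2 of 16 higher, Il33 at 1.45 and Il24 at least 1.40, with Il23a at most -0.91 and Il17a at most -0.80. The TLR, RAGE and NF-kB list (-0.08, 13.6) had no gene higher; Bcl3 was at -1.16, Cd14 at 0.96, Tlr2 at least 0.79 and Tlr6 at -0.51. Immediate early genes (0.02, 75.2) went both ways, with Fosl1 at 1.62 and Nr4a3 at 1.34 but Atf3 at -1.48 and Fos at -0.97. Myelin genes had a lower median (-0.59, 0), with 4 of 21 at least 2-fold lower, including Mag (-1.70), while Pmp2 was higher. Cell cycle genes (0.47, 100; 1 of 33 at least 2-fold higher) and cholesterol synthesis (0.26, 100; 0 of 25) had slightly higher medians; Ccne2 was at 1.07, Cdc6 at 0.83, Ccne1 at 0.78, Cdc45 at 0.73, Hsd17b7 at 0.64, Insig1 at 0.63 and Sc5d at 0.41. Fibroblast and collagen genes had a lower median (-0.28, 0.03; 2 of 15 at least 2-fold lower and 1 higher), with Col6a2 at -1.12, against Postn at 1.02 and Tnc at 0.56. Repair Schwann cell genes (-0.08, 13.8; Ngfr -1.23, Ucn2 -0.72, Gdnf 0.56, Artn -0.53) and macrophage markers (-0.10, 21.9; Lyz2 at most -1.75, Lgals3 -0.59) were not apart; normexp placed the macrophage list apart, at -0.26 (1.83). S100a8, S100a9 and Tlr4 were not well above background on any of the 3 culture arrays, and Ager was at -0.10 ± 0.32. The unstimulated array was of 24 h, so time in culture differs with stimulation here.

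**Figure D2:**
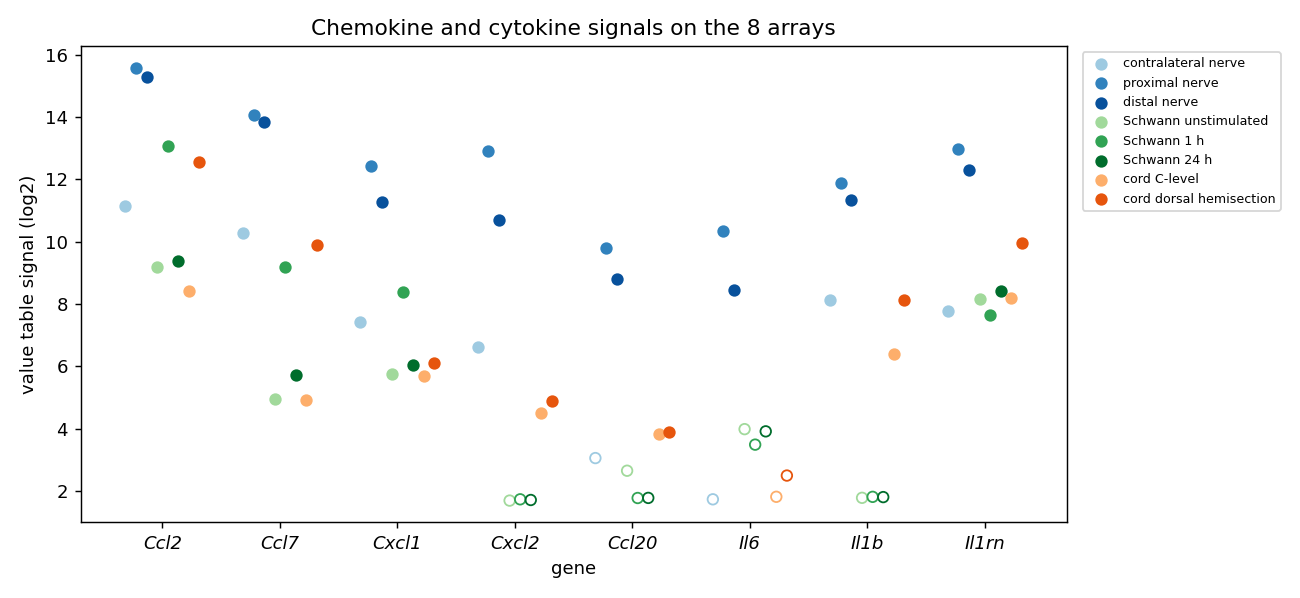
Value table signal (log2, vertical axis) of chemokine and cytokine genes (horizontal axis) on each of the 8 arrays, 1 point per array; open points were not well above background. Ccl2 lies 3.89 higher at 1 h than in unstimulated Schwann cells and 4.16 higher in distal than in contralateral nerve.

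At 24 h the stimulated Schwann cells lay close to the unstimulated ones. The leading ratios were small and mostly of dim genes: Spry3 (2.07 ± 0.35), Npvf (1.97 ± 0.60), Rec114 (1.88 ± 0.51), Ptprv (1.5 ± 0.10), Rfx5 (1.44), Ankrd6 (1.39), Bche (1.32), Lmntd2 (1.27), Thoc2 (1.27) and Ptpro (1.24) were higher. Pom121l2 (-3.02 ± 0.72), Slc8a2 (-1.56), Znrf4 (-1.56 ± 0.11), Bnc2 (-1.54), Pdia5 (-1.48), Kcnma1 (-1.44 ± 0.09), Cstf1 (-1.40), Atf2 (-1.38), Dennd11 (-1.36) and Rtn4ip1 (-1.34) were lower. Of 11025 genes 70 were at least 2-fold higher and 69 lower, fewer than the 121.2 and 120.6 from simulated spot error alone. Those simulated counts can be too high for the same reason as at 1 h. With both arrays well above background 19 were higher and 22 lower, and with normexp 8 and 14. The scans as recorded gave 2689 higher and 2604 lower.

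No chemokine or cytokine was 2-fold apart at 24 h. Chemokines had a median of 0.01 (percentile 56.1), with Ccl7 at 0.75 ± 0.70, Cxcl1 at 0.30, Ccl11 at -0.28 and Ccl9 at 0.23, and cytokines one of -0.03 (33.8), with Il33 at -0.71, Il23a at 0.63, Il11 at -0.49 and Tgfb1 at -0.31. The TLR, RAGE and NF-kB list (0.01, 60.7; Icam1 -0.37, Sod2 0.32, Nfkbia 0.25, Myd88 0.24), immediate early genes (0.07, 95.7; Nr4a3 0.41, Arc 0.36, Ccn2 0.32, Ccn1 0.29), myelin genes (0.08, 92.3; Pmp2 -0.56, Mbp 0.49, Mal 0.44), cholesterol synthesis (-0.03, 25; Hmgcs1 0.36, Fdft1 0.34, Mvd -0.30) and fibroblast genes (0.02, 56.5; Col3a1 0.65, Thy1 0.30, Fbln1 -0.26, and Col14a1 0.26, whose probes disagreed) were not apart. Of 30 lists with a percentile 3 were apart, where lists drawn gene by gene at random would give 1.5. Cell cycle genes had a slightly lower median (-0.23, 0) with no gene of 33 at least 2-fold apart, Kif20a at -0.48, Ttk at -0.39 and Tk1 at -0.36 but Kif11 at 0.42. Endothelial and pericyte markers had a slightly higher median (0.29, 99.99; 1 of 13 at least 2-fold higher), with Cldn5 at least 1.03, Rgs5 at 0.51, Kcnj8 at 0.42 and Kdr at 0.34, and so had MHC class II presentation (0.27, 98.4; 0.09 and 92.5 with normexp), with no gene of 7 at least 2-fold apart. Ager was at 0.04 ± 0.30.

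Between the stimulated times, the ratios of 24 h over 1 h share the 1 h array with the comparison at 1 h, so opposite signs in the 2 are no separate evidence. Ccl2 was at -3.70 ± 0.03, Ccl7 at -3.48 ± 0.40, Calca at -2.89, Pmp2 at -2.84, Hmga2 at -2.45, the inflammatory caspase Casp1 at -2.35, Cxcl1 at -2.33, Adamts1 at -2.25, Spmip7 at -2.19 and Il33 at -2.17. Higher at 24 h were Entpd2 (3.45 ± 0.08), Mfap5 (2.74), Insyn2a (2.54), Gfra3 (2.43), Tktl1 (2.38), Cxcl14 (2.22), Alpl (2.20), Pllp (2.17) and Ugt1a6 (2.0). Myelin genes had a higher median at 24 h (0.72, percentile 100; 7 of 21 at least 2-fold higher and 1 lower; Mag 1.73), and cell cycle genes (-0.71, 0; 3 of 33 lower; Ccne2 -1.22, Cdc6 -1.05, Tk1 -1.0, Tyms -0.97) and cholesterol synthesis (-0.30, 0; 1 of 25 lower; Hsd17b7 -0.66, Acat2 -0.60, Dhcr7 -0.55) had lower ones. Chemokines as a list were not apart (0.03, 59.4), and Ager was at 0.14. Of 10926 genes 203 were at least 2-fold higher and 222 lower, against 102.8 and 113.2 from spot error; normexp gave 110 and 66. With the scans as recorded 2515 were higher and 1959 lower, 9 of 21 named genes had the opposite sign, and the myelin list stood at -0.70.

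The genes higher in injured nerve and in Schwann cells at 1 h were then counted. In the distal nerve and the cells 42 of 10775 genes were at least 2-fold higher in both, where independent lists would give 17.5, and 60 were lower in both, against 16.2. In the proximal nerve and the cells the counts were 43 and 54 of 10819, against 15.0 and 13.1. Ccl2, Ccl7, Cxcl1, Fosl1, Adamts1, Ccne2 and Nr4a3 were higher in all 3 of these comparisons, and Mag, Pllp, Mfap5, Insyn2a and Tktl1 were lower in all 3; these were picked after their values were seen. Opposite moves also exceeded independence: 43 genes were lower in the distal nerve and higher in the cells, against 19, and 21 the reverse, against 15.1. With both arrays well above background 20 and 25 genes were higher in both for the distal and proximal nerve. Normexp left 10 higher and 38 lower with the distal and 11 higher and 26 lower with the proximal nerve. Without a filter or floor the counts were 82 and 106 with the distal and 84 and 98 with the proximal nerve. The scans as recorded, which pair other arrays, gave 182 and 149, and 114 and 566. No expected counts stand beside these, so they cannot be set against those above. At 24 h the overlaps were 8 higher and 12 lower with the distal nerve, against 5.29 and 6.81, and 7 and 11 with the proximal nerve, against 4.59 and 5.52. Opposite moves were no fewer there, with 17 genes lower in the distal nerve and higher in the cells, against 5.70.

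The cord comparison set the sample labelled dorsal hemisection against that labelled C-level control. Macrophage, matrix and cell cycle genes were higher in the dorsal hemisection sample, and neuronal and adipocyte genes were lower. The leading genes were Igsf7 l1 (6.68 ± 0.15), Reg3b (5.53 ± 0.50), the macrophage lectin Siglec1 (5.39 ± 0.09), the matrix protein Postn (5.30 ± 0.38), Hk3 (5.24), Lilrb4 (5.24), Cthrc1 (5.09 ± 0.21), Ccl7 (4.99 ± 0.38), Dapl1 (4.70) and Ifitm1 (4.67 ± 0.06). The lowest were Ucp1, the uncoupling protein of brown fat (-6.25 ± 0.05), Defb1 (-4.98), the glycogen synthase Gys2 (-4.97), resistin, Retn (-4.84 ± 0.10), Ces1d (-4.29), Cox8b (-3.85 ± 0.08), Scgb1c1 (-3.29), Cdh23 (-3.10), Tapbpl (-3.07) and Chad (-3.02). Of 12196 genes 1244 were at least 2-fold higher and 1127 lower, against 39.2 and 48.2 from spot error. Cord level and tissue makeup may differ together with any injury in this pair, as the level of the dorsal hemisection sample is not given. With normexp, which moved the median of all genes by 0.10, 728 were higher and 401 lower. The scans as recorded gave 120 higher and 102 lower, and 27 of 53 named genes had the opposite sign. By rank those scans are the unstimulated and 24 h Schwann cell columns.

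Monocyte and macrophage markers had 14 of 18 higher and none lower (median 1.82, percentile 100), with Msr1 at 3.93, the lysosomal Cd68 at 3.88 and Fcgr2b at 2.38. Microglia markers, some of them shared with that list, had 16 of 20 higher (1.41, 100), with Fcrl2 at 3.30, Trem2 at 1.98 and P2rx4 at 1.83. Neutrophil markers (1.69, 100; 13 of 18 higher) had Mmp8 at least 3.36, Ncf1 at 2.44, Np4 at 2.40 and Trem1 at least 2.17, and S100a8 and S100a9 were at 2.04 ± 0.07 and 1.68 ± 0.07. T and NK cell markers had 6 of 14 higher (0.87, 99.8), with Cd8a at 3.92, Cd3g at 2.25, Cd247 at 1.41 and Cd8b at 1.27. Chemokines had 13 of 29 higher and 3 lower (0.64, 99.99), with Ccl2 at 4.13 ± 0.03, Cxcl13 at 3.58 and Ccl12 at 3.54; cytokines (0.63, 99.9; 7 of 20 higher and 2 lower) had Tgfb1 at 2.15, Il1rn at 1.76, Il1b at 1.73 and Il33 at 1.38. Complement had 11 of 19 higher (1.18, 100), with C5ar1 at 2.52, C3ar1 at 2.31, C1qc at 2.26 and Itgb2 at 2.0, and interferon response genes (0.63, 100; 7 of 28 higher) had Bst2 at 1.95, Gbp2 at 1.69, Ifi47 at 1.49 and Psmb8 at 1.49. Immediate early genes (0.86, 100; 13 of 30 higher and 2 lower) had Fosl1 at 3.80, Atf3 at 3.71, Ccn1 at 2.39 and Ier2 at 1.74. Tlr4 was at 0.76 and Ager at -0.13 (0.12 with normexp).

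Matrix genes were higher in the dorsal hemisection sample. Metalloproteinases and inhibitors had 16 of 28 higher and 1 lower (1.05, 100), with Mmp7 at least 7.02, Mmp12 at least 6.18 and Plau at least 3.75. Fibroblast and collagen genes had 10 of 17 higher and 1 lower (1.28, 100), with Col1a1 at 4.18 ± 0.06, Tnc at 3.58 and Lum at 2.96. Cell cycle genes had 26 of 33 higher (2.07, 100), with Cenpf at least 3.64, Ccnb1 at 3.36, Cdk1 at 3.32 and Ccnb2 at 3.27. Endothelial and pericyte markers (0.54, 99.8; 4 of 18 higher) had Tie1 at 1.78, Acta2 at 1.48, Eng at 1.29 and Pdgfrb at 1.0.

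Neuron markers had 10 of 15 lower and no gene higher (-1.33, 0), with the synaptic Snap25 at -2.36 ± 0.03, the inhibitory transporter Slc32a1 at -2.13 and the GABA-synthesising Gad1 and Gad2 at -1.93 and -1.90. Dorsal horn markers had 8 of 21 lower (-0.90, 0), with Cartpt at -2.25, Nts at -1.76, Tfap2b at -1.74 and Lbx1 at -1.62, while motor neuron and ventral cord markers were not apart (0.05, 63.1; Slc5a7 -1.71, Mmp9 at least 1.69, Lhx4 -1.19, Calcb 1.18). Nerve injury genes of neurons had a low median (-0.62, 0.14; 2 of 16 lower and 2 higher), with Csrp3 at 1.53 and Stmn4 at -1.03. Oligodendrocyte markers had a lower median (-0.57, 0.22; 2 of 17 at least 2-fold lower; Ermn -1.08, Mog -1.05, Mag -0.95). Myelin genes were not apart (-0.01, 69.6), with 6 of 24 higher and 1 lower, among them Pmp2 at 3.41, Prx at 2.73 and Cldn19 at 2.60. Astrocyte markers were not apart (-0.04, 64.8), with Serpina3n at 2.61, Gjb6 at -1.52, Agt at -1.44 and Cd44 at 0.80. Cholesterol synthesis had 5 of 25 lower (-0.70, 0; Insig1 -1.64, Msmo1 -1.40, Hmgcs1 -1.09). Adipocyte markers had 8 of 14 lower and 1 higher (-1.97, 0; -1.08 with normexp and -0.89 with both arrays well above background), with Adipoq at most -6.64, Pck1 at most -4.75 and Cidec at most -2.98, and skeletal muscle markers had 10 of 17 lower and 1 higher (-1.19, 0), with Actn3 at -2.53, Atp2a1 at -2.09, Ckm at -1.83 and Myh2 at -1.80. Of the Hox genes, which mark cord level, the cervical groups were not apart (-0.16, 36.0; Hoxc4 -0.59, Hoxd4 -0.18, Hoxb4 -0.16, Hoxc5 0.15), and of the caudal groups Hoxd9 was at 1.40 ± 0.07, Hoxd10 at least 1.38 and Hoxd12 at -0.60 (0.04 with normexp); their median of 1.38 was 0.40 with both arrays well above background.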

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

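All tests in this part, and the patterns weighed, were chosen after the results were seen. The first pattern is that the value table and the file record pair 7 of 8 samples with different arrays. By ranking the arrays on neuron and on macrophage markers, the markers went with the tissue label in 8 of 8 samples under the value table headings and in 1 of 8 as the scans are recorded. Those counts argue against wrong column headings, at the level of tissues, and go with scans recorded under other samples; as the same markers had part in the choice of the headings, they are no independent check of that choice. Labels within 1 tissue, such as proximal against contralateral nerve, were not tested by this, and no biological explanation was tested.

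The second pattern is the higher skeletal muscle genes in the proximal than in the distal nerve. Scaling between the arrays is argued against, since the list median stayed at -2.55 or lower under the alternatives in scaling and background correction that keep the column headings. Muscle in the proximal piece is a candidate explanation. Of 17 muscle genes 15 were at least 2-fold lower distally, abundant ones such as Ckm (-3.69) and Myh4 (-4.23) among them. That count restates the pattern and does not tell muscle tissue from a change of the nerve. A change of the nerve itself between the segments stays open and was not tested.

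The third pattern is the higher adipocyte genes in the C-level than in the dorsal hemisection cord. Of 14 adipocyte genes 8 were at least 2-fold lower in the dorsal hemisection sample, among them Adipoq (at most -6.64), Retn (-4.84), Pck1 (at most -4.75) and Cidea (-2.33). Ucp1, outside that list, was at -6.25, while Fasn was at -0.89, Scd at -0.52 and Cfd at 1.68. Fat tissue in the C-level piece is neither excluded nor shown by these counts, since those last 3 may come from other cells, and 10 of 17 muscle genes were lower too. A first test, which was dropped, rested on abundant genes of the list, and Retn and Cidea were abundant as well. Scaling between the arrays is argued against as the whole cause, since the list median stayed at -1.08 or lower under the alternatives in scaling and background correction that keep the column headings. A difference by cord level or injury stays open and was not tested.

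Cell cycle genes had medians on opposite sides at the stimulated times, 0.47 at 1 h and -0.23 at 24 h against the same unstimulated Schwann cells, with 1 and 0 of 33 genes at least 2-fold apart. Set against each other, 24 h over 1 h had a median of -0.71 (percentile 0), which describes these 2 arrays; without replicates, a difference between cultures was not tested. Probes without a gene name, which entered no comparison, also held differences. Among those well above background on both arrays, 678 of 7934 were at least 2-fold higher and 862 lower in the distal nerve, and 582 of 8017 higher and 743 lower in the proximal nerve. In the Schwann cells 72 were higher and 32 lower at 1 h, and 34 and 30 at 24 h, while 475 were higher and 609 lower in the dorsal hemisection cord.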

How the results depend on the processing

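The scans as recorded (the design fixed beforehand), and the matched scans with the 75th percentile, normexp, outlier spots kept or all probes, were chosen as alternatives to the value table after seeing the data; the others were fixed before. Quantile normalization within a tissue, median centring and the mean of probes kept all 14 counts of genes within 1.5 times their size. The columns already shared their median and quartiles, so the quantile normalization and the centring could change little and are weak checks of scaling. With normexp on the matched scans 13 of the 14 counts moved beyond that range. Named genes with at least a 2-fold ratio kept their sign where measured, except 3 with normexp and 158 with the scans as recorded. The sizes of named gene ratios were less stable. With normexp 396 of these results were counted as moved in size and 108 as kept. With the matched scans at the 75th percentile 208 were moved and 299 kept, and with the mean of probes 54 were moved. The technical errors after ± do not cover this. Of 115 list results 81 were apart; with the scans as recorded 21 of them stayed apart on the same side, 26 were apart on the other side and 34 were no longer apart, while 19 others became apart. Medians had the same sign in 52 of the 115. Thresholds and filters change the number of genes by construction. The scans as recorded compare other arrays, named here by the column each ranks with. The distal pair was distal nerve over hemisection cord, and the proximal pair Schwann cells at 1 h over that cord. The segments were distal nerve over Schwann cells at 1 h. The Schwann pairs at 1 h and 24 h were contralateral nerve and C-level cord over proximal nerve. The 24 h to 1 h pair was C-level cord over contralateral nerve, and the cord pair unstimulated Schwann cells over those of 24 h. For all other values below the cause was not tested. Signal over background limits the dim genes, whose ratios are bounds.

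At 1.5-fold there were 2927 higher and 2917 lower for distal against contralateral nerve, 2568 higher and 2696 lower for proximal against contralateral nerve, 659 higher and 681 lower for distal against proximal nerve. Counts also included 544 higher and 455 lower for Schwann cells at 1 h, 221 higher and 210 lower for Schwann cells at 24 h, 762 higher and 787 lower for 24 h against 1 h. Beside these were 2323 higher and 2458 lower for the cord. The overlaps were then 2280 higher and 2388 lower for the nerve segments, 224 higher and 229 lower for distal nerve and Schwann cells, 214 higher and 223 lower for proximal nerve and Schwann cells. At 3-fold there were 755 higher and 831 lower for distal against contralateral nerve, 625 higher and 595 lower for proximal against contralateral nerve, 27 higher and 106 lower for distal against proximal nerve. Further counts were 48 higher and 32 lower for Schwann cells at 1 h, 29 higher and 19 lower for Schwann cells at 24 h, 45 higher and 53 lower for 24 h against 1 h. There were also 549 higher and 346 lower for the cord. With both arrays well above background there were 19 higher and 22 lower for Schwann cells at 24 h. Overlaps were 20 higher for distal nerve and Schwann cells, 25 higher for proximal nerve and Schwann cells. Without a filter or floor there were 315 higher and 320 lower for Schwann cells at 1 h, 179 higher and 197 lower for Schwann cells at 24 h, 392 higher and 411 lower for 24 h against 1 h. Shared genes numbered 82 higher and 106 lower for distal nerve and Schwann cells, 84 higher and 98 lower for proximal nerve and Schwann cells. The matched scans at the 75th percentile gave 88 higher and 313 lower for distal against proximal nerve, 182 higher and 227 lower for Schwann cells at 1 h. Keeping the outlier spots gave 89 higher and 313 lower for distal against proximal nerve, 182 higher and 229 lower for Schwann cells at 1 h. All probes of the matched scans gave 96 higher and 340 lower for distal against proximal nerve, 211 higher and 257 lower for Schwann cells at 1 h, 102 higher and 120 lower for Schwann cells at 24 h. Counts also included 319 higher and 271 lower for 24 h against 1 h. The overlaps were then 91 lower for distal nerve and Schwann cells. Normexp on the matched scans gave 1002 higher and 1125 lower for distal against contralateral nerve, 1895 higher and 525 lower for proximal against contralateral nerve, 15 higher and 2223 lower for distal against proximal nerve. Beside these were 48 higher and 87 lower for Schwann cells at 1 h, 8 higher and 14 lower for Schwann cells at 24 h, 110 higher and 66 lower for 24 h against 1 h. Further counts were 728 higher and 401 lower for the cord. Overlaps were 763 higher and 477 lower for the nerve segments, 10 higher and 38 lower for distal nerve and Schwann cells, 11 higher and 26 lower for proximal nerve and Schwann cells. With the sign turned, Rnf148 was at 0.13 for proximal against contralateral nerve, Vip was at -0.32 for distal against proximal nerve and Cenpf was at -0.40 for distal against proximal nerve. The scans as recorded gave 2000 higher and 3649 lower for proximal against contralateral nerve, 2682 higher and 1868 lower for distal against proximal nerve, 1363 higher and 1473 lower for Schwann cells at 1 h. There were also 2689 higher and 2604 lower for Schwann cells at 24 h, 2515 higher and 1959 lower for 24 h against 1 h, 120 higher and 102 lower for the cord. Shared genes numbered 556 higher and 1804 lower for the nerve segments, 182 higher and 149 lower for distal nerve and Schwann cells, 114 higher and 566 lower for proximal nerve and Schwann cells.

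Lists under the scans as recorded changed as follows, with the median log2 ratio after each name. For distal against contralateral nerve complement 0.99, fibroblast and collagen genes 0.71, adipocyte markers 3.05 and microglia markers -1.20 turned to the other side. For distal against contralateral nerve monocyte and macrophage markers 0.56, B cell markers 0.65, interferon response genes 0.37, cholesterol synthesis 0.26, skeletal muscle markers 0.23 and stress genes -0.024 were no longer apart. For distal against contralateral nerve MHC class II presentation 1.88, the S100 family 1.06, immediate early genes 1.19, mast cell markers 4.33 and ribosomal proteins 0.57 became apart. For proximal against contralateral nerve neutrophil markers -3.72, monocyte and macrophage markers -6.04, chemokines -2.48, the TLR pathway -1.01, interferon response genes -2.44, cholesterol synthesis 0.99, skeletal muscle markers -2.41, hypoxia and glycolysis genes -0.53 and microglia markers -5.80 turned to the other side. For proximal against contralateral nerve T and NK cell markers -1.61, B cell markers -2.29, cytokines -1.28, mast cell markers -1.18 and stress genes 0.077 were no longer apart. For proximal against contralateral nerve MHC class II presentation -4.84, the S100 family -2.46 and immediate early genes 0.63 became apart. For distal against proximal nerve skeletal muscle markers 3.20, neutrophil markers 5.59, cytokines 1.42, myelin genes 1.65 and cell cycle genes -1.97 turned to the other side. For distal against proximal nerve metalloproteinases and inhibitors 0.13 and hypoxia and glycolysis genes 0.16 were no longer apart. For distal against proximal nerve chemokines 4.43 became apart. For Schwann cells at 1 h myelin genes 1.24, cell cycle genes -2.35, fibroblast and collagen genes 0.92 and complement 0.37 turned to the other side. For Schwann cells at 1 h chemokines -0.74, cytokines -0.77, the TLR pathway -0.77 and monocyte and macrophage markers -1.42 became apart. For Schwann cells at 24 h endothelial and pericyte markers -0.69 and MHC class II presentation -1.79 turned to the other side. For Schwann cells at 24 h chemokines -2.35, cytokines -1.01, the TLR pathway -1.72, immediate early genes -2.28 and fibroblast and collagen genes -2.78 became apart. For 24 h against 1 h myelin genes -0.70 turned to the other side. For 24 h against 1 h cell cycle genes 0.35 were no longer apart. For 24 h against 1 h chemokines -0.83 became apart. For the cord endothelial and pericyte markers -0.29 and Hox genes of paralog groups 9 to 13 -0.34 turned to the other side. For the cord neutrophil markers 0.04, monocyte and macrophage markers -0.094, microglia markers -0.057, T and NK cell markers 0.056, chemokines -0.001, cytokines 0.049, complement -0.069, interferon response genes -0.047, immediate early genes -0.054, metalloproteinases and inhibitors -0.075, fibroblast and collagen genes 0.023, inhibitory and excitatory neuron markers 0.065, dorsal horn markers 0.095, oligodendrocyte markers -0.13, cholesterol synthesis 0.045, nerve injury genes of neurons -0.0033, adipocyte markers -0.013, skeletal muscle markers 0.056, the TLR pathway 0.0028 and the S100 family 0.032 were no longer apart.

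Named genes with a log2 ratio of opposite sign under the scans as recorded numbered 22, 51, 18, 20, 11, 9 and 27 in the 7 comparisons, among 103, 78, 35, 29, 21, 21 and 53 measured. Distal against contralateral nerve had Or5o1 0.23, Aox4 1.77, Cytl1 0.72, Fam178b 0.43, Blnk -0.91, Mmp7 -3.72, Mmp12 -2.77, Ttk -0.39, Mal 1.12, Hmgcs1 0.26, Nsdhl 0.58 and Igfbp2 -6.14. Next were Col14a1 3.19, Pi16 0.41, Mfap5 2.23, Col1a1 0.84, Arc 0.23, Tnnc2 -0.30, Pck1 2.27, Scd 1.69, Ndrg1 0.83 and Mt2A -0.26. Proximal against contralateral nerve had S100a8 -8.03, Myh4 -2.41, S100a9 -8.18, Myl1 -3.29, Myl11 -3.30, Cxcl2 -2.70, Olr1 -1.0, Ptx3 -4.99, Myh8 -1.75, Ampd1 -0.87, Fam178b 2.61 and Clec4d -1.18. Next were Il1r2 -1.36, Msr1 -5.42, Fcgr2b -7.75, Fcgr1a -10.33, Itgam -7.10, Cd2 -1.45, Cd8a -5.01, Blnk -7.21, Cd79b -1.58, Fcrla -3.81 and Ccl20 -1.77. Next were Il1rn -2.68, Il1b -5.50, Tlr2 -8.24, Tlr6 -5.57, Cd14 -4.11, Bcl3 -1.52, Ifit3 -4.07, Ifi47 -6.0, Psmb8 -5.55, Mmp9 -2.29, Mmp12 -6.17 and C3ar1 -6.12. Next were Itgb2 -7.75, C5ar1 -6.77, Ciita -2.44, RT1-DMb -5.17, RT1-DMa -4.50, Hmgcs1 0.74, Idi1 2.06, Cdh2 2.77, Shh -0.48 and Col14a1 5.21. Next were Postn 4.55, Junb -0.069, Tnnc2 -5.54, Atp2a1 -6.33, Fasn 0.46 and Pparg 1.08. Distal against proximal nerve had Ampd1 0.65, Myl1 4.26, Myh4 4.12, Myf6 0.98, Ckm 5.67, Atp2a1 6.55, Myh8 2.58, Il1r2 3.27, Mmp9 3.43, Cxcl2 7.76, Cxcl6 0.97 and Cxcl1 3.07. Next were Il6 5.56, Cenpf -2.76, Nusap1 -2.26, Plau 2.72, Egln3 1.66 and Slc16a3 3.69. Schwann cells at 1 h had Ccl7 -3.90, Ccl2 -4.70, Cxcl1 -4.94, Adamts1 -1.58, Clec2d2l1 -3.73, Entpd2 0.38, Mfap5 1.53, Insyn2a 2.12, Gfra3 0.77, Alpl 0.88, Pllp 1.70 and Tktl1 1.84. Next were Il33 -0.22, Il24 -0.063, Fosl1 -5.79, Atf3 0.97, Nr4a3 -1.30, Mag 1.27, Ccne2 -2.90 and Col6a2 0.51. Schwann cells at 24 h had Rec114 -0.93, Ptprv -0.44, Rfx5 -1.0, Thoc2 -1.41, Ptpro -2.12, Pom121l2 1.95, Slc8a2 0.92, Znrf4 0.0041, Kcnma1 0.86, Atf2 0.46 and Dennd11 2.38. Schwann cells of 24 h against 1 h had Entpd2 -2.65, Mfap5 -4.15, Gfra3 -0.62, Tktl1 -3.10, Pllp -0.90, Ugt1a6 -1.85, Calca 5.15, Ccne2 1.11 and Tk1 1.80. The cord had Hk3 -1.51, Cthrc1 -0.055, Ccl7 -0.81, Dapl1 -0.23, Ifitm1 -0.26, Cox8b 0.38, Chad 0.36, Ncf1 -0.015, Fcgr2b -0.21, Cd8b -0.20 and Ccl2 -0.21. Next were Il1rn -0.28, Bst2 -0.28, Atf3 -0.018, Ccn1 -0.24, Ier2 -0.023, Plau -0.38, Tnc -0.25, Eng -0.35, Slc32a1 0.041, Tfap2b 0.066 and Calcb -0.085. Next were Prx -0.047, Cldn19 -0.057, Stmn4 0.054, Hoxd9 -0.011 and Hoxd10 -0.72.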

Other observations

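Lists not described above also differed in places. In the distal nerve against the contralateral one microglia markers, many of them shared with macrophages, had a median log2 ratio of 1.06 (percentile 100; 10 of 19 at least 2-fold higher and 1 lower), while oligodendrocyte markers, which overlap the myelin genes, were at -2.0 (percentile 0; 11 of 15 lower). The dorsal hemisection cord had a TLR, RAGE and NF-kB median of 0.80 (percentile 100; 11 of 29 higher), and its S100 family was at 0.72 (percentile 99.98; 4 of 13 higher). Genes at least 2-fold higher in both the distal nerve and the dorsal hemisection cord numbered 612 of 11694, against 158.7 for independent lists, and 329 were lower in both, against 123.0 (359 and 101 with normexp, and 13 and 26 with the scans as recorded); these comparisons share no array. In Schwann cells at 1 h complement genes had a slightly lower median (-0.23, percentile 1.91; 2 of 11 at least 2-fold lower). Neuron (0.29, 99.4) and dorsal horn markers (0.26, 99.3) were apart on the high side there, and 11 of 31 lists were apart. Ribosomal proteins were apart at 1 h (0.06, 98.4) and in the cord (0.13, 99.6), with 0 of 33 genes at least 2-fold apart. Being apart thus does not need a large shift.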
